A study of Mus musculus with 8 samples.

How the data were processed

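RNA of LTi cells from PP and LP of wild-type mice and of mice labelled knockout for Tcf7 was measured in 8 libraries, 2 in each of 4 groups. Per the labels, total RNA was extracted with a miRNeasy Micro kit and libraries were made with Smart-seq2. The deposited values are log2(RPKM + 1) per gene and library on a log2 scale, made by the authors, with 0.0001 written in place of 0. Per the submitters' processing notes, reads per gene were counted with featureCounts of Subread on mm10. Versions, aligner settings, annotation release and strand setting are not given in the sources used here. Per the file headers, the 8 columns share a sequencing lane label. The log base was checked on genes with few reads: after undoing log2, 79.3% of 237 values were whole multiples of the value of 1 read within 0.1 reads, against 60.1% of 233 after undoing a natural logarithm, 31.9% of 235 with no log and 10.8% of 195 after undoing log10. The values set to 0.0001 were read as 0.

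The table gives no counts, so the depth was estimated from the value of 1 read in 976 genes of known length: 28.3 and 32.2 M reads for the wild-type PP libraries, 28.1 and 29.2 for PP labelled knockout, 27.9 and 28.4 for wild-type LP and 30.5 and 28.5 for LP labelled knockout. The quartiles of this estimate over genes were 17.2 and 35.6 M, and PCR reads without molecular identifiers are not independent molecules. Of 27179 Entrez Gene identifiers, 25275 were matched to the RefSeq gene table of GRCm38.p6, the assembly of mm10, for symbols and positions. The other 1904 stayed in the tests, and 847 genes had no symbol.

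Groups were taken from the labels. Genes with at least 1 RPKM in at least 2 of the 8 libraries were kept (10541), and log2(RPKM + 1), with its pseudocount of 1, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of the spread on the mean). All tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. A model with 4 group means and 4 residual degrees of freedom gave the genotype effect in each tissue (labelled knockout minus wild-type), the tissue effect in each genotype (LP minus PP) and their interaction (the genotype effect in LP minus that in PP). An additive model with 5 residual degrees of freedom gave the average genotype and tissue effects. It takes all 8 libraries as independent, which would not hold if PP and LP came from the same mice. Errors of log2 fold changes are the standard errors of these fits, with a median of 1.24 for a comparison of 2 groups and 0.968 for an average effect, and errors of RPKM are SDs. No two-sided permutation test of 2 against 2 libraries can give a p under 0.333, so none was run there. For the comparisons of 4 against 4 libraries, 34 splits of the 8 libraries were counted, the real one included.

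Gene lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The average tissue effect had no list test. The 26 lists, fixed before the data were examined, were B and plasma cell markers, Cell cycle, Effector cytokines, Epithelial cell markers, Glycolysis, Haemoglobin genes, Heat shock genes, ILC1 and NK cell markers, ILC2 markers, ILC3 and LTi identity, Immediate early genes, Interferon response, Lymphoid organ induction, MHC class II and costimulation, Mitochondrially encoded genes, Myeloid cell markers, NF-kB pathway, Notch pathway, Progenitor-associated transcription factors, Respiratory chain (nuclear-encoded), Ribosomal proteins, Stromal and endothelial markers, Survival and apoptosis, T cell markers, Trafficking receptors and Wnt and TCF/LEF pathway. Lists with fewer than 5 genes kept were not tested, which left 24. The fixed choices also set which genes are named. For genotype in PP, genotype in LP and tissue in wild-type these are the 10 largest log2 fold changes per direction among passing genes with a mean of at least 5 RPKM in the higher group and no overlap between the groups. Predicted and unnamed genes were left out. Where fewer than 5 passed in a direction, the list was filled to 5 with the smallest unadjusted p under the same limits. For the interaction, the average genotype effect and tissue in the libraries labelled knockout these are the 5 largest per direction. For each list they are up to 4 passing members with the smallest p. Tcf7 is always named, and any other gene is said to have been named after its values were seen. The results of 1 list member are not reported here.

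The fits were tested on simulated data with the same groups and with replicate deviations drawn from genes of like level, in which 50 genes each were changed by 1, 2, 4 and 6 on the log2 scale. For genotype in PP, 0%, 0%, 24% and 32% of these were found, with 0 unchanged genes called. For genotype in LP, 0%, 14%, 22% and 46% were found, with 1 unchanged gene called. For the average tissue effect, 2%, 22%, 56% and 70% were found, with 1 unchanged gene called. The changed genes had a mean log2(RPKM + 1) at or above that of 5 RPKM, so these shares do not cover weaker genes. Simulated genes kept no spread of their own and varied independently, so the false calls need not carry over to the real data. In a simulation of 20 lists of 20 genes, camera found 3 of 5 lists shifted by 1 and called 0 of the others. Its genes varied independently, so it does not give the rate of false calls for correlated lists. Mitochondrially encoded genes had an estimated correlation of 0.44 for genotype in PP.

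Alternatives fixed before the data were examined were pseudocounts of 0.1, 0.5 and 5, no filter, a filter at 5 RPKM, median-of-ratios rescaling, quantile normalization, a robust spread, library quality weights, a minimum 2-fold change, fits of only the groups compared, a block for the replicate number, and leaving out each library. For the lists they were the estimated correlation and fry, a rotation test of limma. Added after seeing the data were a test without immunoglobulin and mitochondrial genes, a rescaling to the total without them, and a filter on the mean log2(RPKM + 1) of at least 5. Median-of-ratios rescaling moved the median log2 fold change of all genes from 0.155 to -0.068 for genotype in PP, -0.062 to 0.054 for genotype in LP, 0.085 to -0.028 for tissue in wild-type, -0.29 to 0.015 for tissue in libraries labelled knockout, -0.393 to 0.164 for the interaction and 0.087 to -0.025 for the average genotype effect. Because of the pseudocount it moves abundant genes more than weak ones, up to 0.58, -0.22, 0.34, -0.46, -0.80 and 0.18 in the same order. Values were drawn with Python 3.11.15 and matplotlib 3.10.9. Read-level data were not used here.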

Results

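Lymphoid tissue inducer (LTi) cells, innate lymphoid cells known for starting the formation of lymphoid organs, were sorted from mouse Peyer's patches (PP) and from the lamina propria of the small intestine (LP). The gate took live, lineage-negative cells with CD127 and CCR6 on the surface and without KLRG1, NK1.1 and NKp46. The mice were Tcf7+/+ (wild-type) or Tcf7fl/fl with Cre (the knockout label). Tcf7 encodes TCF-1, a transcription factor that acts with beta-catenin in the Wnt pathway. Total RNA was sequenced after Smart-seq2, a method that amplifies cDNA from very few cells by PCR. The 4 groups held 2 libraries each (n = 2 at every value given with an SD below), and the labels do not say whether the 2 came from separate animals, so every p-value measures only the spread between these libraries.

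The table holds 27179 genes as RPKM on a log scale and no read counts. From its lowest values, the depth was estimated at 27.9 to 32.2 M assigned reads per library. Genes at 1 RPKM or more numbered 6411 and 6365 in the wild-type PP libraries, 8103 and 8039 in those labelled knockout, 8192 and 8433 in wild-type LP, and 7437 and 7843 in LP labelled knockout. Correlations of log2(RPKM + 1) across the 10541 genes kept were 0.515 to 0.745 over all pairs of libraries, and genes are not independent replicates. Mitochondrially encoded genes took 13.4% and 13.6% of the summed RPKM in the PP libraries labelled knockout, and 3.06% to 5.06% in the other 6. Immunoglobulin genes, which B lineage cells express, took 2.83% to 6.43% in PP and 10.4% to 17.3% in LP, and the antibodies of the lineage gate are not given in the sources used here. Summed over each marker list, wild-type PP, labelled knockout PP, wild-type LP and labelled knockout LP held 1931, 1649, 503 and 557 RPKM for T cell markers and 636, 949, 629 and 875 RPKM for epithelial markers. B and plasma cell markers summed to 13596, 7268, 31221 and 24842 RPKM, and the 23 myeloid markers to 3571, 3250.5, 1670.5 and 1546 RPKM, most of it from Fcer1g (3079, 2867, 1387 and 1287 RPKM), which innate lymphoid cells also express. In the same order, the sums were 142, 117, 37.9 and 58.2 RPKM for stromal and endothelial markers, and 3.47, 9.74, 1.51 and 6.59 RPKM for haemoglobin genes. Those last lists kept 3 and 2 genes, too few for the list test.

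**Figure D1:**
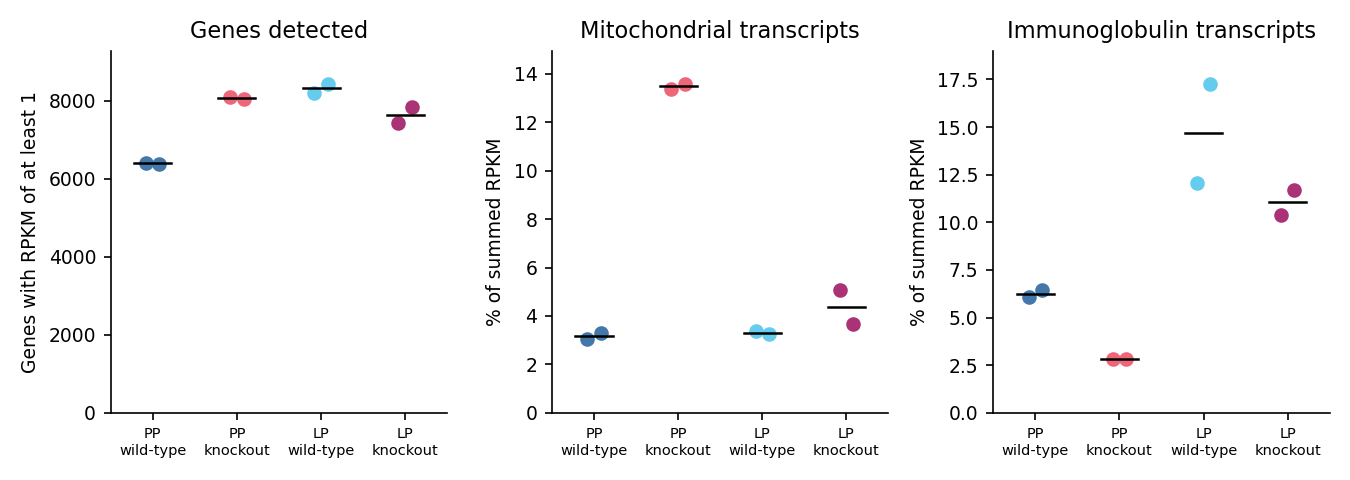
Number of genes at 1 RPKM or more and the shares of the summed RPKM, in percent, from mitochondrially encoded and immunoglobulin genes, on linear axes from 0, each point a library and each bar a group mean (n = 2). Genes at 1 RPKM or more run from 6365 to 8433, and the mitochondrially encoded share of the summed RPKM reaches 13.4% and 13.6% in the PP libraries labelled knockout, against 5.06% at most in the others.

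Tcf7 (Entrez Gene 21414, chromosome 11, 52246527 to 52283383 on GRCm38) was the targeted gene, and no reduction of its transcript passed the test in the libraries labelled knockout. It stood at 164 ± 111 RPKM in wild-type PP and 346 ± 13 RPKM in PP labelled knockout (SD). In LP it stood at 238 ± 12.3 RPKM in wild-type and 226 ± 15.5 RPKM in libraries labelled knockout. The log2 fold change was 1.26 ± 0.48 (SE) in PP, with a limma adjusted p of 0.365, and -0.07 ± 0.48 in LP, with a limma adjusted p of 1. A gene-level RPKM covers the whole gene and does not separate a deleted part from the rest, so the genotype of each library rests on its label alone in all that follows. The PP value was 2.01 without wild-type PP replicate 1 and 0.51 without replicate 2. After median-of-ratios rescaling between libraries it was 0.68, and the LP value turned to 0.15.

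The comparison of genotypes in PP asked which transcripts differ in LTi cells when Tcf7 is targeted, taking the labels as given. It does not separate genotype from a difference in sex. Mean Xist stood at 9.41 RPKM in wild-type and 1.08 in libraries labelled knockout. The Y-linked Ddx3y stood at 0.501 and 5.15, while the Y-linked Kdm5d went the other way, at 9.15 and 0.0186. Il17a (Entrez Gene 16171, chromosome 1, 20730905 to 20734496), which encodes a cytokine of mucosal defence, stood at 0.943 ± 0.188 RPKM in wild-type and 88.8 ± 41 RPKM in libraries labelled knockout, a log2 fold change of 5.45 ± 0.76 (SE, n = 2) with a limma adjusted p of 0.0492. Its relative Il17f, named after its values were seen, stood at 6.06 ± 4.43 and 92.7 ± 27.7 RPKM (limma adjusted p = 0.0529; adjusted over the list alone, 0.00124). Cd7 (Entrez Gene 12516, chromosome 11, 121036747 to 121039478), which encodes a surface protein of T and NK lineage cells, fell from 1607 ± 114 to 467 ± 57.6 RPKM (-1.78 ± 0.23, limma adjusted p = 0.0374). Of the effector cytokine list, 1 of 12 genes rose over all genes tested and 2 when adjusted over the list alone, while the list had a median of -0.05 and a mean of 0.88. That median turned to 0.076 after rescaling to the total without immunoglobulin and mitochondrial genes. The lymphotoxin genes Lta and Ltb did not pass, and were looked up after their values were seen. Lta stood at 631 ± 299.8 and 250.3 ± 26.8 RPKM, and Ltb at 2043 ± 289 and 1977 ± 123. None of the 26 genes of ILC3 and LTi identity and none of the 18 of lymphoid organ induction passed, over all genes or adjusted over the list alone. Their median log2 fold changes were -0.12 and -0.55. The first turned to 0.0055 after rescaling to the total without immunoglobulin and mitochondrial genes. The second stayed negative under each scaling tried, from -1.12 to -0.42, with 13 of the 18 genes negative as deposited.

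Mitochondrially encoded genes rose together in PP libraries labelled knockout: 11 of 15 passed over all genes and 15 adjusted over the list alone, with a median log2 fold change of 2.0. The cytochrome b gene mt-Cytb went from 3238 ± 178 to 12916 ± 614 RPKM (2.0 ± 0.11), mt-Cox3 by 2.2 ± 0.15, mt-Nd1 by 1.99 ± 0.13 and mt-Atp8 by 1.94 ± 0.13. Their camera adjusted p was 2.32e-30, and adjusted p = 0.224 with an estimated correlation. The 77 ribosomal protein genes had a median of -0.42 with 0 passing, a camera adjusted p of 2.47e-07, and adjusted p = 0.507 with an estimated correlation. Epithelial markers had a median of 2.02 over 21 genes, with 0 passing over all genes and 3 adjusted over the list alone, a camera adjusted p of 0.0474, and adjusted p = 0.869 with an estimated correlation. Cldn7, Lgals4 and Reg1, named after their values were seen, went from 0.201, 0.529 and 0.0814 to 45.6, 90.7 and 50.6 RPKM. The direction of these 3 lists was the same under each scaling tried. No list passed with an estimated correlation in any comparison. For the 21 lists that did not pass, the camera adjusted p was 0.094 for Lymphoid organ induction, 0.294 for Respiratory chain (nuclear-encoded), 0.785 for B and plasma cell markers, Effector cytokines, ILC1 and NK cell markers, ILC2 markers, ILC3 and LTi identity, Immediate early genes, Interferon response, MHC class II and costimulation, Myeloid cell markers, NF-kB pathway, Notch pathway, Progenitor-associated transcription factors, Survival and apoptosis, T cell markers and Trafficking receptors, 0.904 for Heat shock genes, 0.908 for Wnt and TCF/LEF pathway, 0.944 for Cell cycle and Glycolysis. Their passing members were Il17a, the lambda constant gene Iglc2 (4.86 ± 0.62) and the immediate early gene Ier5 (5.27 ± 0.69).

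In total 38 of 10541 genes passed for PP, 28 higher and 10 lower in libraries labelled knockout, and 1201 had an unadjusted p under 0.05. Of these 38, 13 were immunoglobulin genes, 11 mitochondrial and 14 others. Immunoglobulin variable (V) segments went both ways: Ighv5-16, Igkv4-74, Ighv9-2, Igkv1-135, Igkv1-133, Igkv12-44, Ighv1-26 and Igkv4-57 were lower, with log2 fold changes of -8.67, -8.18, -7.97, -7.88, -7.71, -7.62, -7.21 and -5.8. Ighv1-82, Ighv9-3 and the joining segments Iglj2 and Igkj4 were higher by 8.2, 7.96, 5.75 and 5.34. V segments of a family share sequence, and how reads shared between them were assigned is not given in the sources used here. The kappa constant gene Igkc, looked up after its values were seen, stood at 11360.0 ± 72.7 and 4558 ± 268 RPKM (limma adjusted p = 0.0617). All 12 other higher genes stood under 2 RPKM in both wild-type PP libraries, among them the galectin gene Lgals2 (0.966 to 155 RPKM), the small GTPase gene Rhog (1.06 to 153), the stress gene Gadd45a (0.469 to 94.9), Mpzl1 (0.418 to 85) and the autophagy gene Becn1 (0.333 to 63.2). Epithelial markers were higher in the same libraries (median 2.02), and whether any of these genes came from admixed cells was not tested. The lower genes outside the immunoglobulin loci were Cd7 and the folate enzyme gene Mthfd2 (47.5 to 0.381 RPKM). The split of 28 higher and 10 lower became 12 and 12 after median-of-ratios rescaling, which moved the median of all genes from 0.155 to -0.068. It was 29 and 3 without wild-type PP replicate 1 and 31 and 4 without replicate 2, with 15 and 18 of the 38 genes shared. The count was 0 with immunoglobulin and mitochondrial genes not tested, 0 with only the PP groups fitted, 76 with no filter, 1 without either PP library labelled knockout, 15 and 14 without wild-type LP replicates 1 and 2, and 24 without either LP library labelled knockout. Il17a passed in 5 of its 23 alternatives and Cd7 in 9, with the direction unchanged in all.

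**Figure D2:**
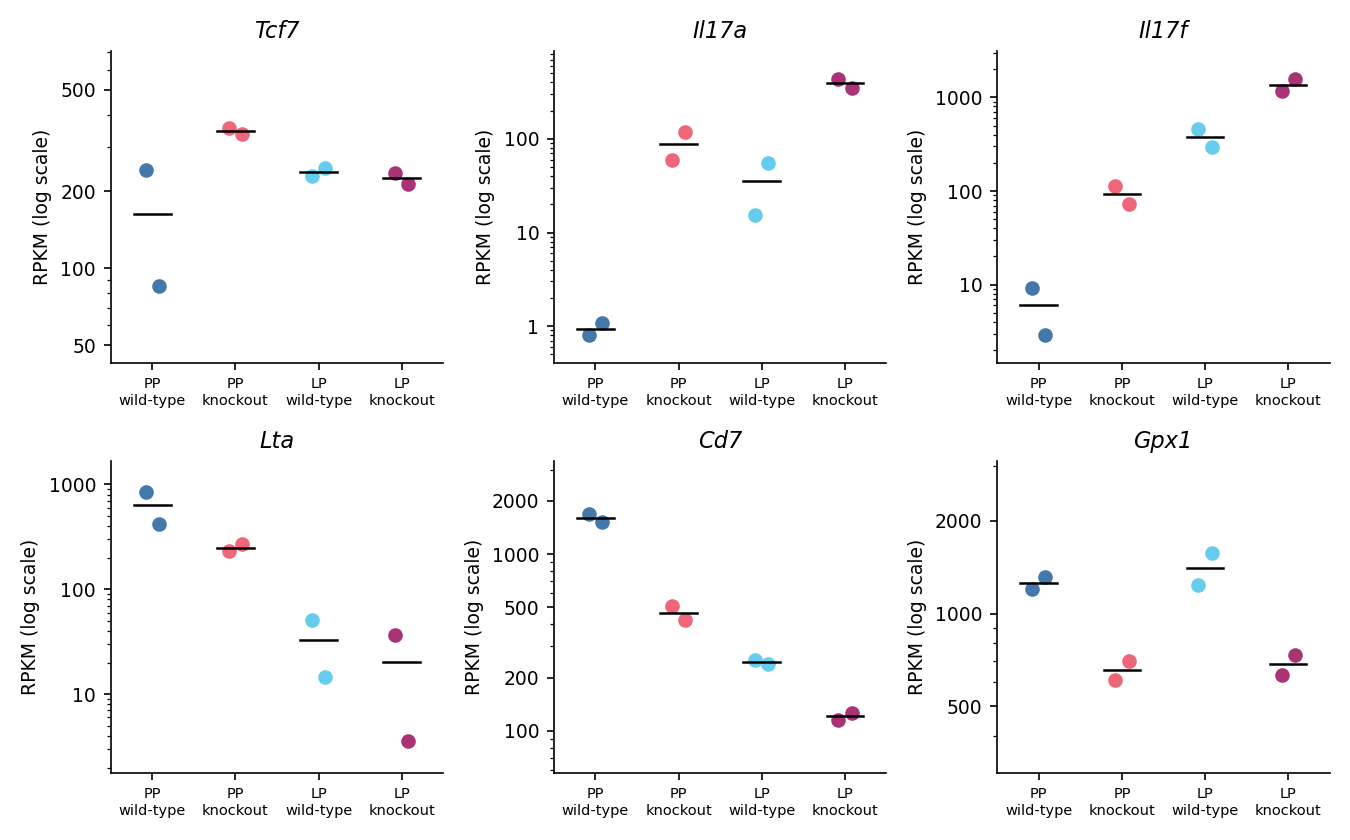
RPKM of Tcf7, Il17a, Il17f, Lta, Cd7 and Gpx1 on log axes, each point a library and each bar a group mean (n = 2). Il17a stands at 0.81 and 1.08 RPKM in wild-type PP and at 59.8 and 118 RPKM in PP libraries labelled knockout, and the Tcf7 means are 164 and 346 RPKM in PP and 238 and 226 RPKM in LP.

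The same comparison in LP gave 3 passing genes, all V segments and all lower in libraries labelled knockout. Ighv5-17 went from 1528 ± 118 to 3.62 ± 0.475 RPKM (SD, n = 2), Ighv8-12 from 2117 ± 945 to 5.73 ± 1.05 and Igkv12-44 from 3452 ± 1730.3 to 27.4 ± 17.8, with log2 fold changes of -8.37, -8.23 and -6.98 and limma adjusted p of 0.0226 for each. Other V segments differed as much between the LP replicates labelled knockout, with Ighv1-9 at 2203 and 1.73 RPKM and Igkv19-93 at 2356 and 6.38. Across the 79 V segments that reached 50 RPKM in at least 1 library, these replicates had r of 0.08, against 0.85 and 0.86 in the PP groups. B lineage cells express immunoglobulin genes, so changes in them need not be changes of LTi cells in any comparison here. Epithelial and T cell markers were also detected, and whether changes in such genes came from other cells was not tested in any comparison. Il17a stood at 35.4 ± 28.6 RPKM in wild-type and 392 ± 63.7 in libraries labelled knockout (3.69 ± 0.76, limma adjusted p = 0.329; adjusted over the list alone, 0.0221, the only gene of the 12 on the list to pass that way). Il17f stood at 376 and 1366 RPKM, Cd7 at 245 and 121, and Gpx1, which encodes glutathione peroxidase, at 1403 and 684. These 3 and Il17a did not pass over all genes, and were named after their values were seen. By the rule for too few passing genes, Gpn2, Tmem171, Ndrg2, Tmprss2 and Ighv1-15 (higher) and Ighv5-4 and Mrpl20 (lower) had the smallest p of the rest, and none passed. Gpn2, Tmem171, Ndrg2 and Tmprss2 went from 0.057, 0.0449, 0.0478 and 0.0247 to 19, 18.6, 14.1 and 14.3 RPKM, and Mrpl20 from 97.3 to 3.83.

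Among the gene lists in LP, 2 of 24 passed camera. Mitochondrially encoded genes had a median of 0.31, with 0 of 15 passing over all genes and 2 adjusted over the list alone (camera adjusted p = 1.34e-05, and adjusted p = 0.705 with an estimated correlation). Ribosomal protein genes had a median of -0.32, with 0 of 77 passing (camera adjusted p = 7.95e-04, and adjusted p = 0.705 with an estimated correlation). Both kept that direction under each scaling tried, but the size moved. After median-of-ratios rescaling the medians were 0.531 for mitochondrially encoded and -0.1 for ribosomal protein genes. The 22 lists that did not pass had camera adjusted p from 0.0803, for effector cytokines, to 0.923. In LP, 556 of 10541 genes had an unadjusted p under 0.05. The replicates labelled knockout differed in sex-linked transcripts, with Xist at 60.3 and 0.0866 RPKM. The count of 3 became 0 with a pseudocount of 0.1, with only the LP groups fitted, and with immunoglobulin and mitochondrial genes not tested, and 56 with no filter. It was 1 with the filter on the mean, and 0 without either PP library labelled knockout, either wild-type LP library or LP replicate 1 labelled knockout.

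Across both tissues, only the V segment Igkv12-44 (Entrez Gene 545851, chromosome 6, 69814631 to 69815100) passed for the average genotype effect, with an average change of -7.3 ± 0.37 (SE, 4 against 4 libraries, limma adjusted p = 1.69e-05). Every SE and p of this effect takes the libraries as independent, which would not hold if PP and LP came from the same mice. Il17a had an average change of 4.57 ± 0.62 and did not pass over all genes (limma adjusted p = 0.105), while adjusted over the list alone it did (2.40e-04), as did Il17f (2.87 ± 0.49, 9.08e-04). Il17f, Cd7 (-1.4 ± 0.23, limma adjusted p = 0.212) and Lta (-1.18 ± 0.66, limma adjusted p = 0.742) were named after their values were seen. By the rule, Sac3d1 (4.86), Ube2l6 (4.56), mt-Nd1 (1.27), mt-Atp8 (1.26), Gpx1 (-0.99), Coq9 (-4.66), Srm (-4.41) and Mir682 (-0.75) had the smallest p of the genes that did not pass. Mitochondrially encoded genes had a median of 1.18, with 0 of 15 passing over all genes and 14 adjusted over the list alone (camera adjusted p = 4.75e-19, and adjusted p = 0.271 with an estimated correlation). Ribosomal protein genes had a median of -0.39, with 0 of 77 passing either way (camera adjusted p = 9.50e-10, and adjusted p = 0.271 with an estimated correlation). The other 22 lists had camera adjusted p of 0.0743 to 0.983, and 718 genes had an unadjusted p under 0.05. The count of 1 was 0 with immunoglobulin and mitochondrial genes not tested, 2 with a pseudocount of 5, 3 with the filter on the mean, and 3 and 4 without LP replicates 1 and 2 labelled knockout.

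The genotype effect differed between tissues for 3 genes, and Tcf7, Il17a, Il17f and Cd7 were not among them. Ighv1-26 went from 1692 to 10.4 RPKM in PP and from 3009 to 1139 in LP, an interaction of 5.77 ± 0.41 (SE, n = 2 per group, limma adjusted p = 0.0182). The short joining segment Igkj4 went from 4.99 to 239 in PP and from 523 to 163 in LP (-7.01 ± 0.54, limma adjusted p = 0.0182). The mitochondrial gene mt-Cytb had -1.64 ± 0.15 (limma adjusted p = 0.0388), and its list had a median of -1.65, with 1 of 15 passing over all genes and 15 adjusted over the list alone (camera adjusted p = 2.98e-23, and adjusted p = 0.356 with an estimated correlation). After median-of-ratios rescaling the median of this list was -0.853, and mt-Cytb did not pass. By the rule, Igkv1-135, Ighv5-16, Igkv4-74 and Ighv9-2 (higher) and Ighv8-12, Ighv9-3 and mt-Cox3 (lower) came next and did not pass. Epithelial cell markers had a median of -4.24 with 0 of 21 passing over all genes (camera adjusted p = 0.283, and adjusted p = 0.879 with an estimated correlation). The 23 lists that did not pass had camera adjusted p of 0.283 to 0.951, and 922 genes had an unadjusted p under 0.05. Across the 10541 genes, the genotype changes of the 2 tissues had a Pearson r of 0.0257 and a Spearman rho of 0.0175, with 50.3% of genes of the same sign. These are values across genes, which are not independent replicates. Igkv12-44 was the gene that passed as lower in both tissues. The count of 3 was 10 with a pseudocount of 5 or the filter on the mean, 36 with no filter, 1 after median-of-ratios rescaling and 0 with immunoglobulin and mitochondrial genes not tested. It was 0 without wild-type PP replicate 1, either PP library labelled knockout, either wild-type LP library or LP replicate 2 labelled knockout, 1 without wild-type PP replicate 2, and 6 without LP replicate 1 labelled knockout.

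The comparison of tissues in wild-type asked how LTi cells of LP differ from those of PP. It does not separate tissue from a difference in sex. Mean Xist stood at 9.41 RPKM in PP and 0.0748 in LP, and mean Ddx3y at 0.501 and 65.1. Mean Kdm5d went the other way, at 9.15 and 1.16. Il22 (Entrez Gene 50929, chromosome 10, 118204584 to 118210047), which encodes a cytokine acting on the epithelium, rose from 725 ± 198 RPKM in PP to 5286 ± 45.5 RPKM in LP (log2 fold change 2.89 ± 0.22 (SE), n = 2, limma adjusted p = 0.00436). Il17f rose from 6.06 ± 4.43 to 376 ± 113 RPKM (5.86 ± 0.55) and Areg, which encodes the growth factor amphiregulin, from 0.529 ± 0.0219 to 107 ± 22.1 (6.12 ± 0.76). The protease gene Furin, named after its values were seen, rose by 2.54 ± 0.47. Ltb, which encodes lymphotoxin beta, fell from 2043 ± 289 to 542 ± 51.8 RPKM (-1.91 ± 0.34, limma adjusted p = 0.0448). Of the 12 genes of the effector cytokine list, which holds Furin, 4 rose and 1 fell over all genes, and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.305 with an estimated correlation). Of the 26 genes of ILC3 and LTi identity 2 rose and 1 fell over all genes, and 2 rose and 5 fell adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.221, and adjusted p = 0.585 with an estimated correlation). Those that rose were Rora (2.49 ± 0.42) and Nfil3. Of the 18 of lymphoid organ induction 1 rose and 1 fell, Ltb, over all genes, and 1 rose and 3 fell adjusted over the list alone, with a median of -0.45 (camera adjusted p = 0.12, and adjusted p = 0.305 with an estimated correlation). Its member Tnfsf11, which encodes RANKL, a signal in lymphoid organ formation, rose from 70.2 ± 52.8 to 866 ± 92 RPKM (3.83 ± 0.55). Genes named after their values were seen and not passing were Lta at 631 ± 299.8 and 32.9 ± 26 RPKM, Il17a at 0.943 ± 0.188 and 35.4 ± 28.6, Id2 at 1805 and 835, Cd4 at 204 and 57.9, and Tbx21 at 0.0233 and 10.6.

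Immediate early genes, induced within minutes of stimulation, were higher in LP: 10 of 24 rose over all genes, and 11 rose and 1 fell adjusted over the list alone, with a median of 1.77 (camera adjusted p = 6.62e-08, and adjusted p = 0.0506 with an estimated correlation). Junb went from 2825 ± 185 to 7721 ± 501 RPKM, Nr4a1 from 62.9 ± 4.82 to 1436 ± 162, Atf3 from 25.2 ± 3.82 to 954 ± 183 and Btg2 from 51 ± 15.6 to 591 ± 52.4. Whether such levels arose in the tissue or during isolation and sorting was not tested, here or in libraries labelled knockout. In the NF-kB pathway 3 of 25 rose over all genes and 7 adjusted over the list alone, with a median of 1.92 (camera adjusted p = 2.30e-05, and adjusted p = 0.144 with an estimated correlation). They were Tnfaip3, whose product A20 restrains the pathway, at 5.09 ± 0.60, Nfkbiz at 3.84 ± 0.46 and Nfkbie at 2.66 ± 0.47. Nuclear respiratory chain genes had a median of -0.67, with 1 of 50 lower over all genes, Cox8a (-1.1 ± 0.19), and 2 adjusted over the list alone (camera adjusted p = 1.85e-05, and adjusted p = 0.0506 with an estimated correlation). T cell markers had a median of -0.96, with 1 of 15 lower over all genes, the gamma constant gene Trgc1 (722 ± 97.7 to 47.1 ± 11.2 RPKM), and 2 adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.305 with an estimated correlation). Progenitor-associated factors had a median of 1.24, with 1 of 18 higher, Nfil3 (2.91 ± 0.52), and the same count adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.305 with an estimated correlation). These 6 lists kept their direction under each scaling tried.

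Members of lists that did not pass also changed in wild-type. Igha, the heavy chain of IgA, rose from 1403 ± 50 to 10947 ± 3397 RPKM (2.93 ± 0.21), Iglc2 rose by 6.08 ± 0.62 and the B cell gene Cd22 fell by 4.87 on the log2 scale, while immunoglobulin genes took 12.1% and 17.3% of the summed RPKM in LP. The granzyme gene Gzmc rose by 5.76 ± 0.77 and Il2rb by 1.54 ± 0.25. Arg1 rose by 1.22 ± 0.22, the chaperone gene Hspa5 by 2.18 ± 0.29 and the chemotactic receptor gene Gpr183 by 1.78 ± 0.26. Cd81 changed by -1.92 ± 0.23, the Fc receptor chain gene Fcer1g by -1.14 ± 0.17 and the nucleotide enzyme gene Rrm2 by -4.7 ± 0.75. By the rule, the largest changes upward were V segments, Nr4a2 (7.17), Mir155 (6.97), Orai1 (6.91), Rnf125 (6.86), Mvk (6.86), Hmces (6.84) and Azin1 (6.68), and Mir155 lies in a host transcript whose reads were not separated from it. The largest downward were V segments, the T cell receptor segments Trbd2 (-8.34) and Trbj2-2 (-6.98), Tuba8 (-7.18) and Ighg2b (-7.06). T cell markers summed to 1931 RPKM in wild-type PP and 503 RPKM in wild-type LP, and whether these receptor segments came from admixed cells was not tested. Epithelial cell markers had a median of 2.27 over 21 genes, with 17 higher in LP and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.067, and adjusted p = 0.564 with an estimated correlation). For the 18 lists that did not pass, the camera adjusted p was 0.067 to 0.879.

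In total 224 of 10541 genes passed between the wild-type tissues, 141 higher and 83 lower in LP, and 1787 had an unadjusted p under 0.05. Immunoglobulin genes were 21 of them. Of the others, 59 of 130 higher genes and 28 of 73 lower genes stood under 2 RPKM in both libraries of the lower group. After median-of-ratios rescaling, which moved the median of all genes from 0.085 to -0.028, 125 were higher and 126 lower. Without wild-type PP replicate 1, 145 were higher and 22 lower, and without replicate 2, 156 and 24, with 103 of the 224 genes shared each time. The count was 0 with only the 2 groups fitted, 1 and 0 without wild-type LP replicates 1 and 2, 88 and 93 without PP replicates 1 and 2 labelled knockout, and 104 and 107 without LP replicates 1 and 2 labelled knockout.

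**Figure D3:**
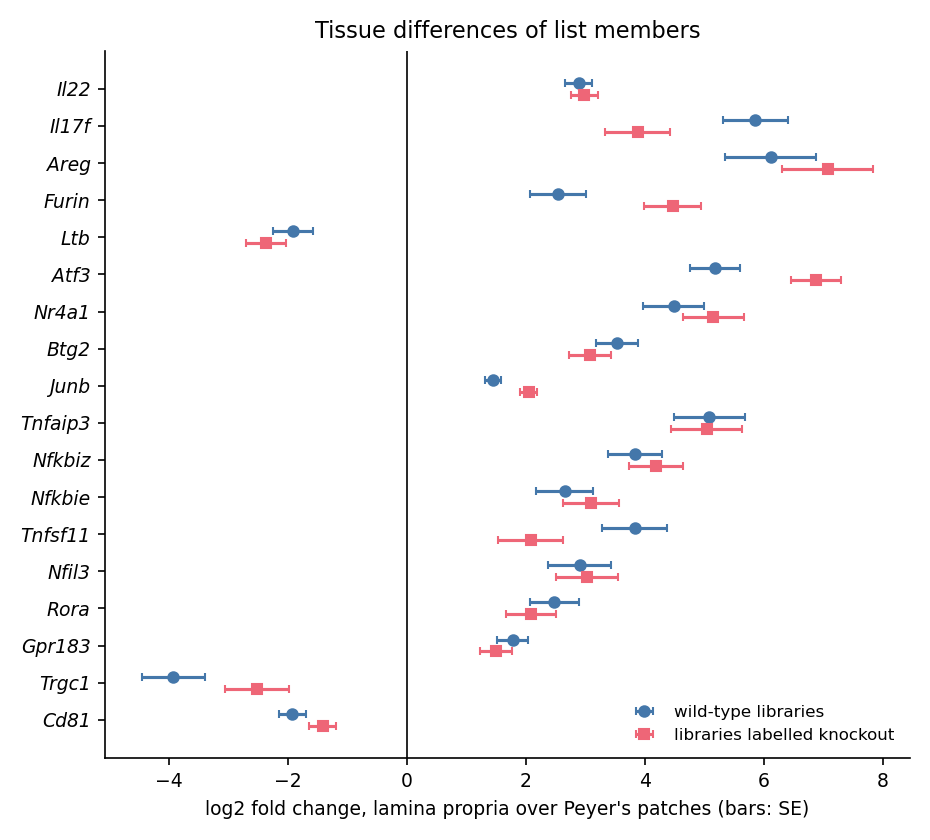
Log2 fold changes of LP over PP for list members on a linear axis, with circles for wild-type libraries, squares for libraries labelled knockout and bars for the SE of the limma fit (n = 2 per group). Il22 stands at 2.89 in wild-type and 2.99 under the knockout label, and Ltb at -1.91 and -2.37.

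Between the tissues of mice labelled knockout, Il22 rose from 538 ± 109.8 RPKM in PP to 4235 ± 265 RPKM in LP (2.99 ± 0.22 (SE), n = 2, limma adjusted p = 0.00366). Il17f rose by 3.88 ± 0.55, Areg by 7.08 ± 0.76 and Furin by 4.47 ± 0.47, and Ltb fell from 1977 ± 123 to 409.6 ± 208 RPKM, so that 4 of the 12 genes of the effector cytokine list, the protease gene Furin among them, rose and 1 fell (adjusted over the list alone, 6 and 2). Their median was 2.59 (camera adjusted p = 9.87e-04, and adjusted p = 0.223 with an estimated correlation). Of the 26 genes of ILC3 and LTi identity 1 rose, Nfil3 (3.04 ± 0.52), and 1 fell over all genes, and 2 rose and 4 fell adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.402, and adjusted p = 0.794 with an estimated correlation). Mitochondrially encoded genes were lower in LP, 12 of 15 over all genes and 15 adjusted over the list alone, with a median of -1.82 (camera adjusted p = 3.18e-23, and adjusted p = 0.0893 with an estimated correlation). They took 13.4% and 13.6% of the summed RPKM in PP against 5.06% and 3.67% in LP. The changes of mt-Cytb, mt-Cox3, mt-Atp8 and mt-Nd1 were -1.96, -2.2, -1.64 and -1.63. Immediate early genes had a median of 1.89, with 8 of 24 higher and 1 lower over all genes, Fos (-1.32 ± 0.20, named after its values were seen), and 10 and 3 adjusted over the list alone (camera adjusted p = 9.50e-08, and adjusted p = 0.0563 with an estimated correlation). Their members with the smallest p were Atf3 (6.88 ± 0.42), Junb (2.05 ± 0.14), Nr4a1 (5.15 ± 0.51) and Btg2 (3.09 ± 0.35).

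NF-kB pathway genes of libraries labelled knockout had a median of 1.53, with 5 of 25 higher in LP over all genes and 8 adjusted over the list alone (camera adjusted p = 3.16e-08, and adjusted p = 0.0632 with an estimated correlation). Tnfaip3 rose by 5.04 ± 0.60, Nfkbiz by 4.19 ± 0.46, Nfkbie by 3.1 ± 0.47 and Nfkbia by 2.0 ± 0.25. Heat shock genes had a median of 0.72, with 1 of 14 higher both ways, Hspa5 at 1.9 ± 0.29 (camera adjusted p = 0.0025, and adjusted p = 0.106 with an estimated correlation). Nuclear respiratory chain genes had a median of -0.68, with 0 of 50 passing over all genes and 2 lower adjusted over the list alone (camera adjusted p = 1.82e-05, and adjusted p = 0.0563 with an estimated correlation). T cell markers had a median of -1.9, with 2 of 15 lower over all genes, Trgc4 (-5.46 ± 0.77) and Cd8b1 (-4.11 ± 0.73), and 4 adjusted over the list alone (camera adjusted p = 0.00654, and adjusted p = 0.257 with an estimated correlation). These 7 lists kept their direction under each scaling tried, and the other 17 had camera adjusted p of 0.0957 to 0.973. Among the members of those 17, Igkc (1.74), Igha (2.23), Gzmb (5.92), Gzmc (7.33), Hk2 (4.36) and Gpr183 (1.5) were higher in LP, and Cd79b (-2.76), Fcrla (-4.43), Xcl1 (-5.96), Cd81 (-1.41) and Fcer1g (-1.15) were lower. Other large changes were the chemokine genes Cxcl2 (7.53) and Cxcl10 (7.15), the V segments Ighv1-15 (7.11), Ighv9-3 (-8.28), Ighv1-82 (-7.95) and Ighv9-1 (-6.54), Sash3 (-6.75) and the gut hormone gene Gip (-6.48).

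In total 211 of 10541 genes passed between the tissues labelled knockout, 98 higher and 113 lower in LP, and 1551 had an unadjusted p under 0.05. Immunoglobulin genes were 14 of them and mitochondrial genes 12. Of the others, 22 of 92 higher and 58 of 93 lower genes stood under 2 RPKM in both libraries of the lower group. The split became 126 higher and 62 lower after median-of-ratios rescaling, which moved the median of all genes from -0.29 to 0.015, and 129 and 97 after quantile normalization. It was 109 and 61 without wild-type PP replicate 1 and 108 and 60 without replicate 2, with 139 and 138 of the 211 genes shared. The count was 0 with only the 2 groups fitted, 30 and 25 without PP replicates 1 and 2 labelled knockout, 32 and 35 without wild-type LP replicates 1 and 2, and 37 and 45 without LP replicates 1 and 2 labelled knockout.

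Over both genotypes, Gem, Il22, Crem, Atf3 and Nr4a1, named after their values were seen, were higher in LP. The GTPase gene Gem changed by 3.62 ± 0.17 (SE, 4 against 4 libraries, limma adjusted p = 7.47e-06), from 192 and 168 RPKM in PP to 2595 and 1896 in LP. Il22 changed by 2.94 ± 0.16, the cAMP-responsive factor gene Crem by 5.0 ± 0.29, Atf3 by 6.03 ± 0.43 and Nr4a1 by 4.82 ± 0.36, with limma adjusted p of 1.47e-05, 2.15e-05, 5.73e-05 and 7.18e-05. In total 456 genes passed, 242 higher and 214 lower in LP, and 2040 had an unadjusted p under 0.05. Of the passing genes, 16 were immunoglobulin genes, 1 was mitochondrial and 439 were others. Higher and lower genes numbered 330 and 211 after quantile normalization, 230 and 167 after median-of-ratios rescaling, and 274 and 286 with a pseudocount of 5. The count was 282 with no filter, 294 and 298 without PP replicates 1 and 2 labelled knockout, and 243 and 245 without wild-type LP replicates 1 and 2.

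**Figure D4:**
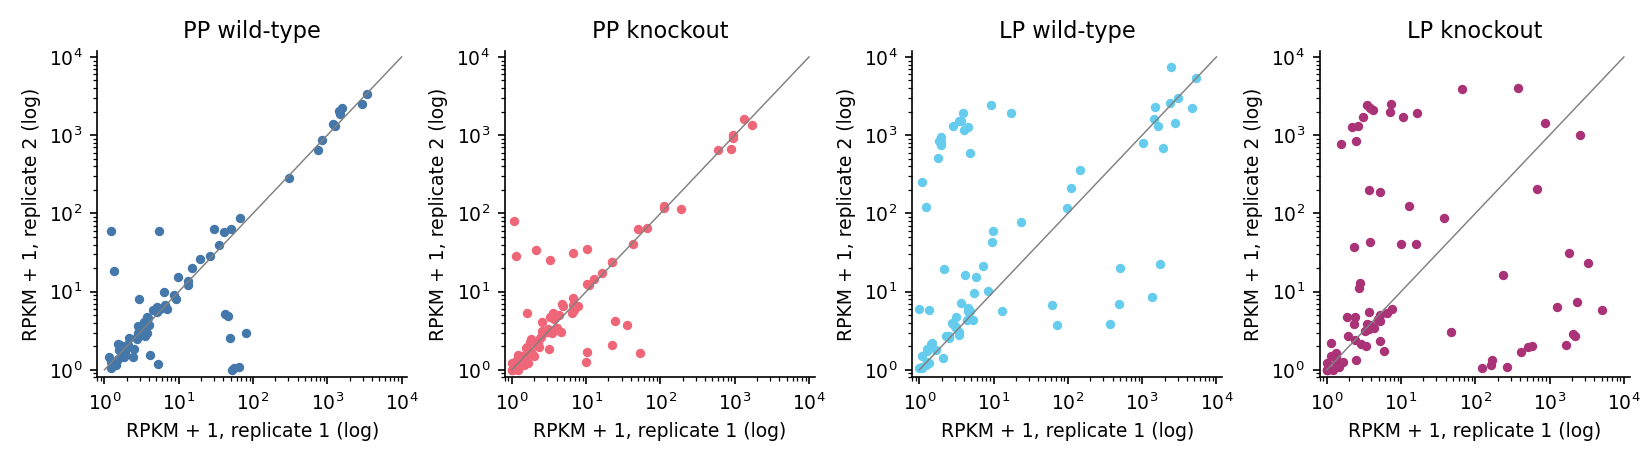
RPKM + 1 of 79 immunoglobulin V segments in replicate 1 against replicate 2 of each group, on log axes with equal limits, each point a segment and the line marking equal values. The correlations of log2(RPKM + 1) across segments are 0.85 and 0.86 in wild-type and knockout-labelled PP, and 0.52 and 0.08 in LP.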

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

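The tests of scaling, capture between the wild-type tissues, ribosomal protein genes, agreement of V segments between groups, reads crossing between libraries and the counts of splits were chosen after the result was seen. The other tests given here were written down before the values they measure were seen.

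The test of the difference between tissues passed for Ighv1-26 (5.77 on the log2 scale, LP effect minus PP effect), for Igkj4 (-7.01) and for mt-Cytb (-1.64). It also passed camera for the mitochondrially encoded list (median -1.65, and -0.853 after median-of-ratios rescaling), with adjusted p = 0.356 with an estimated correlation.

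Mitochondrially encoded transcripts were higher in the PP libraries labelled knockout, with a median change of 2.0. Scaling between libraries is argued against as the whole cause, since 5 of the genes still passed after median-of-ratios rescaling, with a median of 1.42. Poorer capture in the wild-type PP libraries is argued against as the whole cause, assuming like mitochondrial levels in both wild-type tissues (not tested). Wild-type LP had more genes at 1 RPKM or more (8192 and 8433 against 6411 and 6365) and would then stand above wild-type PP, while the mitochondrial genes had a median of -0.199 for LP minus PP in wild-type (quartiles -0.283 and -0.038), against -1.82 in libraries labelled knockout. An earlier test of capture decides nothing: 115 nuclear genes at a mean of 500 RPKM or more had a median of -0.23 for genotype in PP, but the summed RPKM of the PP libraries differed by a factor of 1.02 at most, and a fixed total keeps abundant genes from rising together. Damaged cells or RNA quality could have raised these transcripts: the ribosomal protein genes had a median of -0.42, which such damage and a change in the cells would both allow, so the explanations cannot be told apart by it. An effect of the targeted gene stays open as a biological explanation, untested.

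Immunoglobulin V segments were alike between the PP replicates, with r of 0.85 and 0.86 across 79 segments, against -0.04 to 0.35 between libraries of different groups. A use of the same segments by all animals is argued against by that highest value of 0.352. The segments were chosen for reaching 50 RPKM in at least 1 library, which can lower correlations between groups. The same 79 segments gave the higher values within PP. Reads crossing between libraries are argued against by 16 segments above 200 RPKM, which stood in the other replicate at a median of 103% (quartiles 89.3% and 118%). A shared source of both PP replicates, such as a pool or the same animals, may explain the pattern. Over 60 weaker segments, under 50 RPKM in every library, the lower of the PP correlations was still 0.549. It was 0.517 in wild-type LP, near 0 in LP labelled knockout and -0.39 to 0.30 between groups. Other values go both ways. The wild-type PP replicates correlated at 0.577 over the 10541 genes kept, below the 0.583 to 0.596 between wild-type and knockout-labelled PP libraries, and at 0.672 against 0.687 to 0.717 over 880 other abundant genes, and stood at 115 and -146 on the second principal component. The PP replicates labelled knockout correlated above these pairs, at 0.655 and 0.841. Y-linked transcripts differed between PP replicates, with Kdm5d at 0.00944 and 18.3 RPKM in wild-type and Eif2s3y at 40.7 and 0.141 RPKM under the knockout label. A shared source therefore stays open. No biological explanation was tested, and with a shared source the p-values would not cover the spread between animals.

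Transcripts abundant elsewhere were seen at a low level in libraries that lacked them, at a median of 0.674% to 0.891% of their mean in the others, over 206 to 586 genes per library. The medians were 0.701% in PP and 0.827% in LP, a ratio of 1.18, which does not decide on low expression that differs by tissue. The genes were chosen for a low level in the library and a high mean in the others, which keeps the medians low in both tissues. Reads assigned to the wrong library may be the source, since this level followed the level in the other libraries in each of the 8, with a lowest Spearman correlation across genes of 0.435 and a highest of 0.733. A low true expression in every group was not tested, and no biological explanation was tested. Il17a in wild-type PP replicate 1, at 0.81 RPKM, stood at 0.549% of its mean in the other libraries, against the median of 0.674% in that library.

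Chance cannot be excluded for the average genotype effect, for which 2 of 34 splits of the libraries gave as many genes as the real 1, with 1 as the highest of the others. For the average tissue effect only the real split of 34 gave 456 genes, with 0 as the highest of the others. That does not exclude chance: the other splits mix the tissues, which leaves the tissue difference in the spread and keeps their counts low. Chance between animals cannot be excluded either while a shared source of replicates stays open, since the splits then part libraries that are not independent.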

How the results depend on the processing

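The 3 alternatives on immunoglobulin and mitochondrial genes and on the mean were chosen after seeing the data, and where a value changed its cause was not tested unless given. Leaving out 1 library leaves a group with a lone library, which is assumed to vary like the others. The Tcf7 change in PP kept its sign and did not pass under any alternative, at 0.51 to 2.01 with 1 library left out, and in LP it turned to 0.15 after median-of-ratios rescaling. With 1 library left out, the counts were 1 to 35 for genotype in PP (38 as reported), 0 to 4 for genotype in LP (3), 0 to 180 for tissue in wild-type (224), 25 to 170 for tissue in libraries labelled knockout (211), 0 to 6 for the interaction (3), 1 to 4 for the average genotype effect (1) and 243 to 448 for the average tissue effect (456). With only the groups compared, which leaves fewer libraries for the spread, the counts were 0 for genotype in PP and in LP and 0 for tissue in wild-type and in libraries labelled knockout. Deviations of samples with the same replicate number correlated at -0.02 to 0.01 across genes between groups, which gives no sign of pairing by number. It cannot exclude pairing, since the labels do not say which animals the libraries came from. A block for the replicate numbers leaves fewer residual degrees of freedom, and still fewer when nested in tissue. The block gave 16, 0, 99, 74 and 1 for genotype in PP, genotype in LP, tissue in wild-type, tissue in libraries labelled knockout and the interaction. Nested in tissue it gave 1, 0, 6, 12 and 0 for these, and 257 for the average tissue effect. No filter gave 76 for genotype in PP, 56 in LP, 36 for the interaction and 282 for the average tissue effect. Genotype in PP also gave 24 after median-of-ratios rescaling, 23 after quantile normalization and 21 with library quality weights. A pseudocount of 0.1 gave 0 for genotype in LP, and a pseudocount of 5 gave 10 for the interaction and 2 for the average genotype effect. Median-of-ratios rescaling gave 1 for the interaction. Not testing immunoglobulin and mitochondrial genes gave 0 for genotype in LP, the interaction and the average genotype effect, where it removes each passing gene by construction. It also gave 0 for genotype in PP, where 14 of the 38 genes were others: these were still tested and lost their calls through the adjustment, which alone gives 0, with the fold changes as before (Il17a at 5.45). The filter on the mean gave 1 for genotype in LP, 10 for the interaction and 3 for the average genotype effect. The correlation of the genotype changes between tissues (0.0257) was 0.0399 with a pseudocount of 5, 0.0174 with no filter, 0.00591 after quantile normalization, 0.0170 without immunoglobulin and mitochondrial genes, 0.132 with the filter on the mean and 0.0109 to 0.0318 with 1 library left out.

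With an estimated correlation the lists passing were 0 in every comparison, against 3, 2, 6, 7, 1 and 2 for genotype in PP, genotype in LP, tissue in wild-type, tissue in libraries labelled knockout, the interaction and the average genotype effect. Median-of-ratios rescaling gave 5 for genotype in PP, 12 for tissue in wild-type, 3 for the interaction and 5 for the average genotype effect. Directional fry, which asks whether a list moves on balance, gave 1 for genotype in PP, 0 in LP and 0 for the average genotype effect. For tissue in wild-type and in libraries labelled knockout, its adjusted p was 9.41e-04 and 0.00157 for immediate early genes. It was 0.00116 and 0.0012 for nuclear respiratory chain genes, and 0.088 and 0.00981 for T cell markers. The estimated correlations of immediate early and respiratory chain genes were -0.0035 and -0.018, below the preset 0.01. Higher correlation was thus not what raised their camera p. Mixed fry, which asks for changes in either direction, gave 12 for genotype in PP, 22 and 20 for the tissue effects, 6 for the interaction and 5 for the average genotype effect. Of 179 single-gene results, 132 passed, 11 of them under every alternative run, and 47 did not, 32 of them under none. Over 3940 values, 2932 kept direction and side of the threshold, 960 lost the call, 42 gained it and 6 turned. Those that turned did not pass: Ltb for genotype in PP at 0.029 after quantile normalization, 0.087 after rescaling to the total without immunoglobulin and mitochondrial genes, 0.10 without wild-type PP replicate 2 and 0.021 without PP replicate 2 labelled knockout, and Lta at 0.41 and Ltb at 0.043 for genotype in LP without LP replicate 2 labelled knockout. With 1 library left out these ran from -0.19 to 0.10, -2.64 to 0.41 and -1.04 to 0.043. The median SE of 1.24 limits what can pass between groups, and the depth is known only as an estimate.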

Other observations

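Further genes passed for the average tissue effect, named after their values were seen and all higher in LP (4 against 4 libraries). The autophagy receptor gene Sqstm1 changed by 3.0 ± 0.18 (SE, limma adjusted p = 2.62e-05), from 285 ± 46.1 and 296 ± 56.7 RPKM in PP to 2298 ± 5.07 and 2364 ± 580.3 in LP (SD, n = 2). Vps37b, of the machinery that sorts proteins into endosomes, changed by 4.6 ± 0.29, the stress gene Gadd45b by 4.71 ± 0.30, the tRNA synthetase gene Eprs by 4.94 ± 0.34 and Cd83, a surface marker of activated cells, by 2.81 ± 0.22. Their limma adjusted p were 3.00e-05, 3.26e-05, 4.62e-05 and 1.13e-04. These 5 passed under every alternative run for this comparison.

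Sex-linked transcripts differed within and between groups. Xist stood at 60.3 RPKM in LP replicate 1 labelled knockout and at 0.0866, 0.0712 and 0.0784 in the other LP libraries, where the Y-linked Ddx3y stood at 0.312 against 67.5, 58.9 and 71.3 RPKM. In PP, Xist stood at 9.6 and 9.22 RPKM in wild-type and 0.326 and 1.84 in libraries labelled knockout, and Ddx3y at 0.779 and 0.223 and at 8.93 and 1.36. The PP replicates also differed in other Y-linked genes, with Kdm5d at 0.00944 and 18.3 RPKM and Eif2s3y at 0.116 and 5.25 in wild-type, and Eif2s3y at 40.7 and 0.141 in libraries labelled knockout. The long non-coding RNA Malat1 stood at 1318 RPKM in LP replicate 1 labelled knockout and at 384 to 533 in the other libraries. Of the genes of the gate, Il7r (CD127) stood at 206 to 454 RPKM and Ccr6 at 89.3 to 597, and Ncr1 (NKp46) was listed at 0 in all 8 libraries. Klrb1c (NK1.1) reached 32.8 RPKM in wild-type PP replicate 1 and Klrg1 10.7 in wild-type LP replicate 1.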
